A study of Danio rerio with 22 samples.

How the data were processed

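Total RNA was extracted from pools of 30 to 50 embryos kept at 28.5 °C, per the labels' protocols; 800 ng was linearly amplified with amino-allyl nucleotides and 5 µg of each amplified RNA was coupled to Cy5 or Cy3. Each array held mtx2 MO and std MO RNA of 1 stage, and the series describes the arrays of a stage as biological replicates with dye swaps. Several arrays of a stage come from the same labelled day, under different clutch labels where these are given, so part of the agreement between them may be that of a shared day, and p-values measure the spread between these arrays.

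The deposited scanner files give, per the file headers, ImaGene spot values of both channels as linear intensity with a background intensity of its own for each spot, not normalized. Per the file headers 1 channel is red and the other green, and this matched the labelled dyes on all 22 arrays. An array held 16896 spots in 32 blocks of 24 rows and 22 columns, with 557 control spots and 16339 spots of 16177 distinct probes. A quality flag accompanies each spot; the meaning of its codes is not given in the sources used here and was read from the criterion columns of the same files. Spots with codes 1 (manual), 3 (failed a measurement criterion) or 4 (negative) were left out, 0.1 to 33.6% of the probe spots of an array, and spots with code 2 (empty) were kept.

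The authors' deposited value table holds log2 ratios, 1 per probe and array; limma is named in the submitters' processing notes, with no version. Its scale, centring and direction are unstated. Set against log2 red over green of each array, its columns correlated positively on all 13 second-campaign arrays (r from 0.62 to 0.91 across probes) and negatively on all 9 first-campaign arrays. The negative values ran from -0.89 to -0.52 apart from 30% epiboly replicate 12, where r was -0.13. So the direction was read from the data, and it stays less sure for replicates 10 and 12, whose columns matched another array more closely. For replicate 12 that array was 30% epiboly replicate 6 (r of size 0.43), and for replicate 10 it was replicate 11 (0.56, against 0.52 with its own). The column medians were -0.43, -0.8, -1.46, 0.04, 0.13, -0.04, 0.02, -0.19, -0.23, -0.16, -0.25 and -0.36 for 30% epiboly replicates 1 to 12, -0.63, -0.65, -0.94, -0.97 and -1.17 for shield replicates 1 to 5, and -0.99, -1.24, -0.75, -1.49 and -2.3 for tailbud replicates 1 to 5. The values were thus not centred per array, and how they were scaled stays unknown. The table was used as an alternative only, centred on each column's median.

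The scanner files were analysed in R 4.3.3 with limma 3.58.1. Signal means were corrected with normexp (offset 50) on all spots and normalized within arrays by global loess, with control spots and left-out spots at weight 0. Spots of 1 probe were averaged. A probe was kept when either channel exceeded its background by 2 background SDs on at least 50% of the arrays of at least 1 stage, which kept 16102 probes and dropped 75. The fit (lmFit and eBayes) had 5 terms over all 22 arrays, the mtx2 MO effect at each of 3 stages, with the sign set by the labelled dyes, and a dye effect for each campaign. All arrays shared 1 spread per probe. Contrasts between stages came from refits of the same model, and the test over stages compared it with a model that has 1 effect for all stages, with the moderated variance. Benjamini-Hochberg adjusted p-values under 0.05 counted as changes. For std MO embryos, single-channel log2 intensities of the 13 second-campaign arrays (Aquantile between arrays) were tested over stages with the dye as a covariate.

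Identifiers of the scanner files and of the value table differ by 1 letter and otherwise matched for all 16177 probes. No table given here pairs them with genes, and 1 probe that carries a RefSeq accession was named through a gene table of assembly GRCz12tu. The rule for named genes, set before the data were examined, asked for a gene symbol and up to 10 probes per direction and stage; none of the probes that passed had a symbol. The 19 gene lists were therefore not tested. The 4 identifiers in the text were chosen after their values were seen. They are the 2 with the lowest mean ratio among probes called at all 3 stages, and the 2 highest at tailbud among called probes that were higher on 5 of 5 arrays. The symbol rarga is reported because it was the 1 symbol available.

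Shield and tailbud replicates of the same number share the day in the labels, and the clutch where a clutch label is given. The pairing was taken from there. Deviations of same-numbered arrays from their stage means correlated weakly (r from -0.025 to 0.136 across probes), and 0 of 5 shield arrays deviated most like the tailbud array of their own number. The ratios themselves had a median r of 0.471 (5 pairs, 0.272 to 0.54) for same-numbered arrays. For different numbers with the same dye orientation it was 0.428 (8 pairs, 0.065 to 0.54). How much a shared day adds is not settled by these values. 30% epiboly numbers do not pair with those of shield and tailbud. Residual SD was 0.092 in the first campaign and 0.261 in the second (median over probes).

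The fits were tested on simulated data with 200 changed probes per stage among 16102. With 1 spread for all arrays, 97% of 1.5-fold changes were recovered at 30% epiboly, 88.1% at shield and 77.6% at tailbud, with 3%, 5.9% and 4.2% of calls being unchanged probes. With each campaign's own spread, the share of unchanged probes among calls was 1% at 30% epiboly, 52.7% at shield and 46.9% at tailbud; fitting the second campaign alone brought it to 18.8%, 8.9% and 10.9%, and recovered 17.9%, 62.7% and 70.1% of 1.5-fold changes. For the test over stages, with 1 spread 5.5% of calls were unchanged probes, and 32% with each campaign's own spread. For the stage change in std MO embryos, 45.5% of 3-fold and 6% of 2-fold changes were recovered.

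Alternatives covered the background correction, the normalization, the filter on dim probes, flags, the dye term, separate fits, array weights, collection day and replicate number as blocks, averaging by day, each campaign alone, the value table, the variance model and leaving out each array; turning replicate 6, signal medians, keeping flagged spots, a minimum of 3 values, 3 arrays per stage from the same 3 days and the agreement of stages on arrays that share no day were added after seeing the data.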

Results

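Gene expression was compared in zebrafish embryos injected with an antisense morpholino against mtx2 (mtx2 MO) or with a standard control morpholino (std MO), at 3 stages from the late blastula to the end of gastrulation. A morpholino is a modified oligonucleotide that blocks translation or splicing of its target RNA, so the level of the target RNA need not report how well it worked. The gene then called mtx2, now mxtx2, encodes a homeodomain transcription factor of the Mix family that acts in the yolk syncytial layer, the extraembryonic layer under the blastoderm that takes part in epiboly, the spreading of the blastoderm over the yolk. Each of 22 2-colour oligonucleotide arrays paired mtx2 MO RNA with std MO RNA of the same stage, 12 arrays at 30% epiboly, 5 at shield and 5 at tailbud. The mtx2 MO RNA carried Cy5 on 6 arrays at 30% epiboly and on 2 arrays at each later stage. All values below are log2 ratios of mtx2 MO over std MO, so that a negative value is a lower level in mtx2 MO embryos. The arrays compare these injections only, so other effects of the morpholino cannot be told apart from a loss of mtx2.

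The arrays fell into 2 campaigns by the labelled days of collection. The first held 9 arrays, all of 30% epiboly, and the second held 3 arrays of 30% epiboly and all arrays of the later stages. Median red signal was 6.78 to 13.2 times background in the first campaign and 1.53 to 4.32 times in the second, where the lowest value belonged to tailbud replicate 5. Median green signal was 6.29 to 10.8 times background in the first campaign and 4.85 to 8.99 times in the second. The SD of the ratios across probes was 0.224 to 0.271 on first-campaign arrays and 0.343 to 0.606 on second-campaign arrays. The number of arrays limits the precision of every value given here. Probes carry design identifiers, and the tables used here give a gene symbol for 1 probe of 16177, that of rarga, a retinoic acid receptor; the results are therefore counts of probes, and 4 probes are followed by their identifiers. The probe for mtx2 could not be picked out, and 19 gene lists fixed beforehand could not be tested.

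The first question was which probes differ between mtx2 MO and std MO embryos at 30% epiboly, a late blastula stage. At this stage 103 probes fell and 12 rose in mtx2 MO embryos, of 16102 tested with limma at an adjusted p of 0.05. The changes were lopsided in size as well. With the dyes as labelled, 40 probes fell by more than 1 on the log2 scale and 0 rose by more than 1. With the sign of 30% epiboly replicate 6 turned, 67 fell and 0 rose by more than 1, and without that array 68 and 0. In limma, 892 probes had an unadjusted p under 0.05 in either direction with the dyes as labelled. Without any effect a share of 0.05 of the 16102 tested would pass, and 892 lies little above that share. CGENXEB_456009281_0 had a log2 ratio of -3.42 (SE 0.25, adjusted p 6.24e-07), a 10.7-fold lower level in mtx2 MO embryos. It was lower on 8 of the 8 arrays with a usable spot (mean -3.42 ± 0.66, SD, n = 8), and its spot was saturated on 4 of these, which compresses a ratio. Replicates 4 to 7 of 30% epiboly, replicate 6 included, had no usable spot for this probe. CGENXEB_456006350_0 had a log2 ratio of -2.33 (SE 0.33, adjusted p 0.00105), a 5.02-fold lower level, and was lower on 11 of 12 arrays. The probe of rarga stood at -0.03 (SE 0.06, adjusted p 1) and did not pass the test.

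The direction of 1 array, 30% epiboly replicate 6, is not settled. With the dyes as labelled, its ratios correlated negatively with those of each of the other 8 first-campaign arrays (r from -0.876 to -0.304 across probes, which are not independent replicates), whereas the 28 pairs among those 8 arrays all correlated positively (r from 0.072 to 0.929). With its sign turned, 315 probes fell and 93 rose at 30% epiboly; without it, 270 fell and 68 rose, and the 115 probes called with the dyes as labelled were called in the same direction in both settings. With its sign turned, CGENXEB_456006350_0 stood at -2.68 (adjusted p 2.42e-10). The 3 second-campaign arrays gave 48 falls and 5 rises at this stage when that campaign was fitted alone, and the first campaign alone gave 6 falls and 0 rises as labelled. With replicate 6 turned, the first campaign alone gave 1617 falls and 1234 rises. Without any 1 of the other first-campaign arrays 50 to 60 probes were called. With collection day as a random block 34 fell and 1 rose, and after scaling between arrays 274 fell and 104 rose.

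**Figure D1:**
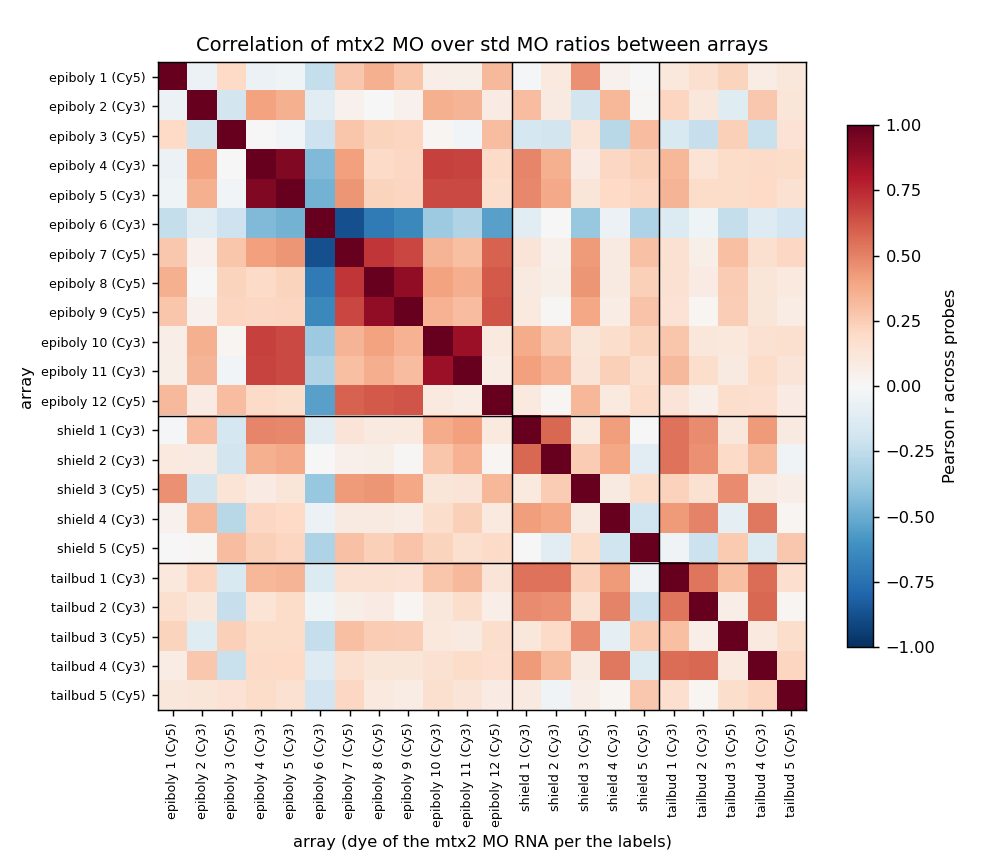
Pearson correlation across probes of the mtx2 MO over std MO log2 ratios for every pair of the 22 arrays, with both axes listing the arrays and the labelled dye of the mtx2 MO RNA; black lines part the 3 stages. 30% epiboly replicate 6 is blue against the other first-campaign arrays, replicates 4 to 12, with r down to -0.876.

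At shield stage, when the embryonic organizer forms, 472 probes fell and 420 rose of 15344 tested. Most of the large changes were again falls, with 88 probes falling and 16 rising by more than 1 on the log2 scale. CGENXEB_456009281_0 stood at -4.21 (SE 0.32, adjusted p 6.07e-07), an 18.5-fold lower level, with close values on all 5 arrays (mean -4.27 ± 0.16, SD, n = 5). CGENXEB_456006350_0 stood at -3.52 (SE 0.51, adjusted p 0.00031), an 11.5-fold lower level, and was lower on 5 of 5 arrays. CGENXEB_456001647_0 was 1.44-fold higher in mtx2 MO embryos (log2 ratio 0.53, SE 0.1, adjusted p 0.00422), higher on 5 of 5 arrays, but its adjusted p was 0.0604 with the second campaign alone. The probe of rarga stood at 0.2 (SE 0.09, adjusted p 0.207).

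The number of smaller changes at shield rests on how the spread is estimated, since the fit over 22 arrays takes much of its spread from the quieter first campaign, which held no shield array. With the second campaign alone 154 probes fell and 29 rose at shield. In simulated ratios given each campaign's own spread, with 200 changed probes per stage, the fit over 22 arrays called 215 unchanged probes at shield, 52.7% of its calls, against 17 (8.9%) when the second campaign was fitted alone. The share depends on how many probes were set to change and is not the share among the 892. Of the 892 shield calls, 109 rested on fewer than 3 arrays with a value. Median centring without loess gave 282 falls and 140 rises, and without shield replicate 2 the count was 416.

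At tailbud, the end of gastrulation, 746 probes fell and 949 rose of 15560 tested. Here too the changes above 1 on the log2 scale were mostly falls, 168 against 16 rises. CGENXEB_456009281_0 stood at -3.51 (SE 0.32, adjusted p 4.86e-07), an 11.4-fold lower level, with values that spread widely (mean -3.57 ± 1.34, SD, n = 5) and a saturated spot on 1 of the 5 arrays, so this fold is less exact than that at shield. CGENXEB_456006350_0 stood at -3.68 (SE 0.51, adjusted p 3.62e-05), a 12.8-fold lower level; both were lower on 5 of 5 arrays. CGENXEB_456005483_0 was 3.31-fold higher in mtx2 MO embryos (log2 ratio 1.73, SE 0.13, adjusted p 4.46e-09), and CGENXEB_456001647_0 was 2.48-fold higher (1.31, SE 0.1, adjusted p 6.49e-09), each on 5 of 5 arrays. Both were chosen as the highest called probes at this stage that were higher on 5 of 5 arrays, so that agreement is fixed by the choice. The probe of rarga stood at 0 (SE 0.09, adjusted p 0.986). With the second campaign alone 314 probes fell and 145 rose, so that the majority of rises was lost; in the simulation the fit over 22 arrays called 169 unchanged probes at tailbud, against 22 with the second campaign alone. The split also turned under other normalizations, with 873 falls and 509 rises after print-tip loess, 701 and 547 after median centring alone, and 224 and 188 after scaling between arrays. Without tailbud replicate 2 the count was 1082, and 124 of the 1695 calls rested on fewer than 3 arrays with a value.

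**Figure D2:**
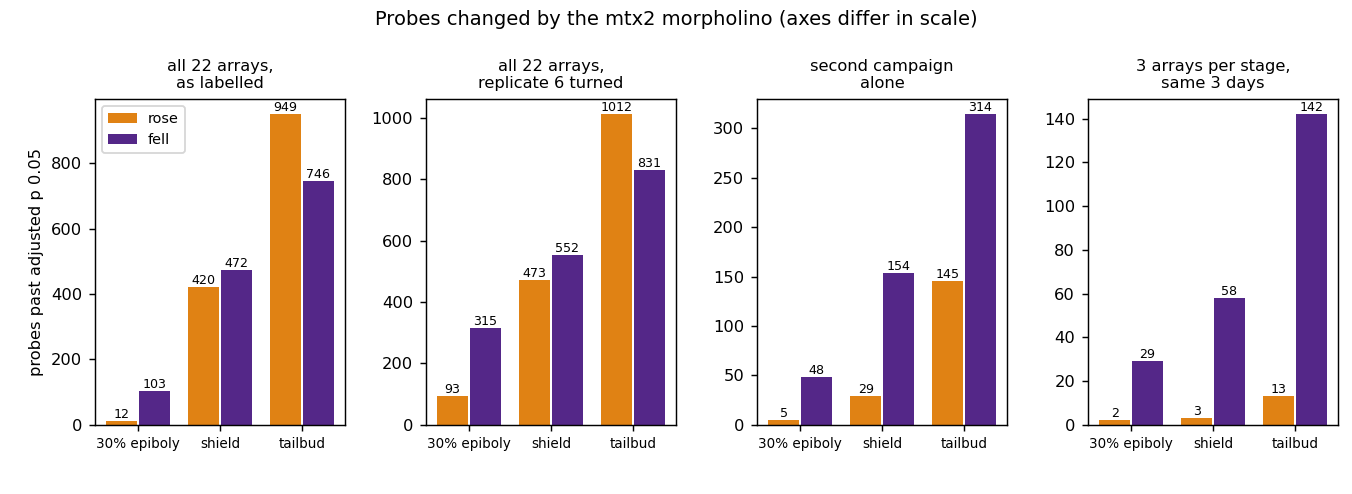
Number of probes past an adjusted p of 0.05 (vertical axes, which differ in scale) that rose (orange) or fell (purple) in mtx2 MO embryos at each stage, in 4 fits. With the second campaign alone falls outnumber rises at every stage, 48 to 5, 154 to 29 and 314 to 145.

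The next question was whether the response to mtx2 MO is shared between stages. Of the probes called at all 3 stages, 24 fell at each stage and 0 rose at each with 30% epiboly replicate 6 as labelled, 91 and 7 with it turned, and 81 and 3 without it. With the second campaign alone 22 probes were called at all 3 stages, of which 21 fell throughout. Shield and tailbud shared 155 falls (22.1 expected for independent lists among the 15167 probes tested in both) and 138 rises (24.7 expected), and 11 probes were called in opposite directions. Falls at 30% epiboly were shared with shield for 44 probes (3.05 expected) and with tailbud for 34 (4.79 expected). Rises at 30% epiboly were shared with shield for 0 probes (0.328 expected) and with tailbud for 1 (0.732 expected). With replicate 6 turned, 135 falls at 30% epiboly were shared with shield (10.1 expected) and 122 with tailbud (15.9 expected), and 17 rises were shared with shield (2.47 expected) and 19 with tailbud (5.33 expected), while 5 and 20 probes were called in opposite directions. Across probes, which are not independent replicates, the log2 ratios correlated between stages with r = 0.49 for 30% epiboly and shield, 0.48 for shield and tailbud and 0.36 for 30% epiboly and tailbud. The stages share the dye terms of the fit, and simulated arrays without any effect gave mean r between -0.01 and 0.016. Second-campaign arrays of different stages also share days, and clutches where these are labelled, which neither this simulation nor the expected overlaps include. The stages further share 1 spread per probe, so a probe whose spread is estimated too small is prone to be called at several stages. The expected overlaps leave this out and are too low by an unknown amount, although a shared spread does not by itself favour the same direction. On arrays that share no day, r was 0.5 for 30% epiboly and shield and 0.34 for 30% epiboly and tailbud (first campaign as labelled against the second), and 0.25 to 0.41 for shield and tailbud over 4 dye-balanced divisions of the days.

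**Figure D3:**
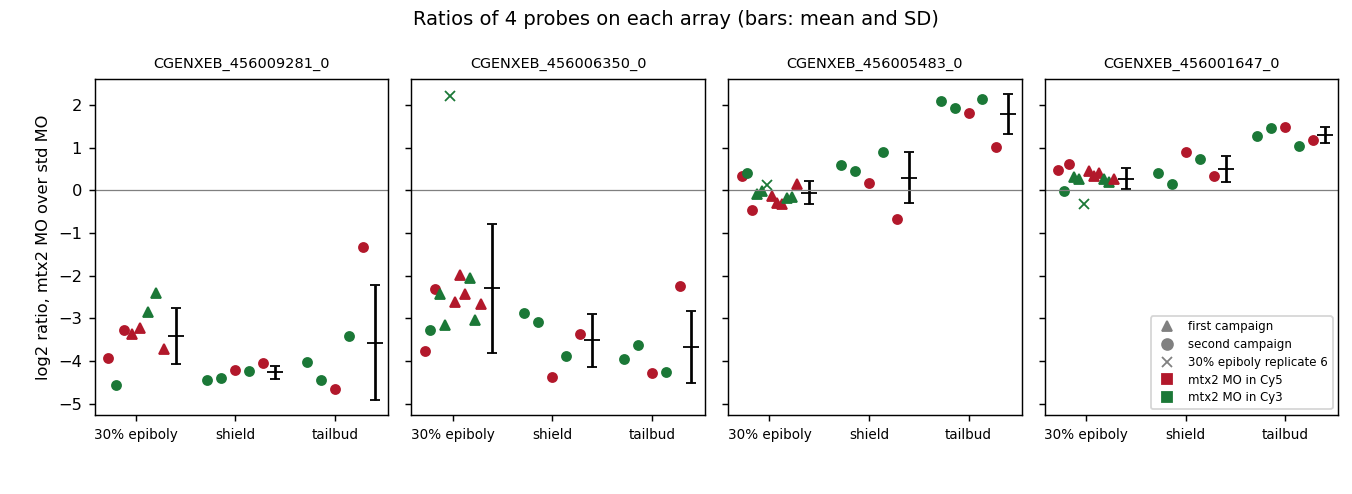
Log2 ratio of mtx2 MO over std MO (vertical axis) of 4 probes on each array with a value, by stage; triangles are first-campaign arrays, circles second-campaign arrays, the cross is 30% epiboly replicate 6, colour gives the dye of the mtx2 MO RNA, and black bars are the mean and SD. The 2 probes on the left were lower at every stage, with replicate 6 as the exception in CGENXEB_456006350_0. Replicate 6 has no value for CGENXEB_456009281_0. The 2 probes on the right were higher at tailbud on 5 of 5 arrays. All were chosen by such values.

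The difference between stages was tested directly. The mtx2 MO effect differed between stages for 642 of 15167 probes (F test in limma), with 156 probes past the threshold for shield against 30% epiboly, 231 for tailbud against shield and 689 for tailbud against 30% epiboly. With 30% epiboly replicate 6 turned these counts were 800, 207, 290 and 885. Of the 12 arrays of 30% epiboly, 9 are of the first campaign, while all later arrays are of the second. The 642 and the contrasts with 30% epiboly therefore partly set campaigns against each other, with 1 shared spread. In simulated ratios with each campaign's own spread, 32% of the calls of the F test over 22 arrays were unchanged probes. CGENXEB_456005483_0 was among the 642 (F test adjusted p 4.9e-07), with log2 ratios of -0.03, 0.22 and 1.73 from 30% epiboly to tailbud, and so was CGENXEB_456001647_0 (adjusted p 3.19e-05), with 0.27, 0.53 and 1.31. Both had been chosen for a high ratio at tailbud, which favours a small p in this test. The strongly lowered probes CGENXEB_456009281_0 (adjusted p 0.42) and CGENXEB_456006350_0 (adjusted p 0.255) did not pass this test. These 2 had been chosen among probes called at all 3 stages, which favours like effects over the stages and a large p here. In tailbud against shield, 147 of the 231 probes had a lower ratio at tailbud; these averaged 0.04 at shield and -1.1 at tailbud. The other 84 averaged -0.4 at shield and 0.42 at tailbud. Shield and tailbud arrays of the same replicate number share a collection label, and pairing them by that number left 85 probes, 63 lower and 22 higher at tailbud, of which 68 were among the 231. With the second campaign alone, where stage is not mixed with campaign, 116 probes differed between stages. In the fit over both campaigns without 30% epiboly replicate 1 the count was 1006.

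The std MO channel of the second campaign gave the change of expression over the same stages without knockdown. Of 14611 probes, 2009 changed between stages (F test in limma), with 200 probes higher and 283 lower at shield than at 30% epiboly, and 481 higher and 539 lower at tailbud than at shield. The probe of rarga was 2.48 higher on the log2 scale at tailbud than at shield (SE 0.31, adjusted p 8.91e-05), a change several times its SE, and stood at -0.22 from 30% epiboly to shield (SE 0.37, adjusted p 0.878). Both strongly lowered probes were higher at tailbud than at 30% epiboly in std MO embryos, CGENXEB_456009281_0 by 2.05 (SE 0.31, adjusted p 0.000197; its spot was saturated on 1 tailbud array, which compresses this value) and CGENXEB_456006350_0 by 1.71 (SE 0.31, adjusted p 0.000821). The probes that were higher in mtx2 MO embryos at tailbud did not pass this test, with F test adjusted p 0.501 for CGENXEB_456005483_0 and 0.502 for CGENXEB_456001647_0.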

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

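The tests of exchanged dyes and of an opposite response for 30% epiboly replicate 6, of the spread taken from the first campaign, of 3 arrays per stage, of turning whole days and of exchanging stages within days were chosen only after the result was seen; the others in this part were set before.

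30% epiboly replicate 6 ran against the other 8 first-campaign arrays with the dyes as labelled. Its red over green ratios were regressed on the mtx2 MO and dye profiles of those 8 arrays, which gave an effect slope of -1 by the label, where the other arrays gave 0.67 to 1.05, and a dye slope of 0.66, where they gave 0.55 to 0.98. An exchange of the red and green scans in the file is argued against, since it needs a dye slope below 0. RNAs coupled to the dyes opposite to the labels may account for the pattern, as they need a slope of about -1 with an ordinary dye slope. A response of these embryos in the opposite direction gives the same effect slope of -1 and stays open, because no value here separates it from exchanged dyes.

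More probes were called at tailbud than at 30% epiboly, 1695 against 115. The quieter first campaign may raise the later counts through the shared spread, but it does not by itself account for this order, as the second campaign alone gave 8.66 times as many calls at tailbud as at 30% epiboly. Nor does the number of arrays, as 3 arrays per stage from the same 3 days, with the same dye orientations, gave 155 calls at tailbud, 61 at shield and 31 at 30% epiboly, a ratio of 5. Other settings gave another order. Array weights, which favour the first campaign, gave 3775 calls at 30% epiboly, 83 at shield and 403 at tailbud, scaling between arrays gave 378, 60 and 412, and the first campaign alone with replicate 6 turned gave 2851 at 30% epiboly. The counts therefore do not rank the responses, and whether the response is larger at the later stage stays open.

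Differences between stages drew attention to 642 probes (F test), to CGENXEB_456005483_0 (adjusted p 4.9e-07) and to CGENXEB_456001647_0 (adjusted p 3.19e-05). The median red signal of tailbud replicate 5 was 1.53 times background, where the other 4 tailbud arrays had 2.99 to 3.47; its gap was 0.753 of the range of the 5 arrays. This was 1 of 22 sets of values looked at for distant arrays, and chance gives about 1 in 20. Without tailbud replicate 5, CGENXEB_456009281_0 stood at -4.12 at tailbud and CGENXEB_456006350_0 at -4.15. Among the 22 kinds of control feature outside the comparisons, 21 were brighter than the blank spots in both channels, which were at 1.58 times background in red and 2.32 times in green.

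Other assignments of the mtx2 MO and std MO RNAs to the channels were counted for each stage. At 30% epiboly, 2 of 100 assignments, the real one included, gave 115 calls or more, so chance can be excluded at this level if the arrays count as independent; the highest other count, 167, came from turning replicates 4, 5, 6, 10 and 11, all the first-campaign arrays with mtx2 MO in Cy3. All 9 first-campaign arrays then have 1 orientation, so that the dye term takes up their effect and replicates 1 to 3 set the estimate. Turning replicate 6 alone, which was not among the 100 drawn, gave 408 calls. The 12 arrays come from 6 days, and with all arrays of a day turned together 1 of 32 assignments, the real one, gave 115 or more and the highest other gave 3, so chance can be excluded for whole days too, although the count itself is 35 with collection day as a random block. At shield and at tailbud 16 assignments are too few for a share under 0.05: the real assignment gave 892 and 1695, the highest other 545 and 658, and 1 of 16 at each stage gave as many as the real one. Of 100 allocations of the 13 second-campaign arrays to the stages, 4 gave 642 or more probes with an effect that differs between stages, but these ignore the days that the stages share, and the highest other gave 2265, several times the real count. Such a count points to a structure of the samples, which was not identified: its groups mixed days and dyes, and in the simulation unequal spread of the campaigns gave 257 unchanged probes in this test. With stages exchanged within collection days only, 2 of 100 allocations, the real one included, gave 642 or more. The highest other gave 912, and further allocations gave 613, 580 and 575. This does not settle whether chance gives such a count. The test was chosen after the result was seen, and its fit is the one that called the 257 unchanged probes. With the second campaign alone the count itself is 116, and no allocations were counted for that fit. For the stage change in std MO embryos 1 of 100 allocations, the real one with 2009 probes, gave as many, and the highest other gave 1250; within days it was again 1 of 100, with 1301 as the highest other, so chance can be excluded.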

How the results depend on the processing

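Turning 30% epiboly replicate 6, signal medians, keeping flagged spots, a minimum of 3 values, the first campaign alone with replicate 6 turned and 3 arrays per stage from the same 3 days were chosen after seeing the data; the other settings were set before. The cause of each shift below was not tested unless stated. CGENXEB_456009281_0 was lower and past the threshold at all 3 stages in every setting (47 at 30% epiboly, 45 at each later stage), and CGENXEB_456005483_0 and CGENXEB_456001647_0 were higher and past it at tailbud in all 45. These probes were chosen for strong ratios in the main fit of the same arrays, so passing in other settings is favoured by that choice. The size of the change in CGENXEB_456009281_0 did move. Apart from leaving out 1 array, its log2 ratio ran from -4.67 to -1.4 at 30% epiboly, -4.27 to -2.81 at shield and -3.72 to -2.27 at tailbud. CGENXEB_456006350_0 was lower in every setting, but missed the threshold in 2 of 47 at 30% epiboly, 2 of 45 at shield and 1 of 45 at tailbud. CGENXEB_456001647_0 missed it at shield in 8 of 45 and passed it at 30% epiboly in 10 of 47. The count of probes that change between stages (2009 in std MO embryos) stayed within 1.5 times, from 1458 to 2639, in all 25 settings, including collection day as a block. These settings include the mtx2 MO channel in place of the std MO channel, which gives the stage change of mtx2 MO embryos.

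The counts of mtx2 MO calls moved more. At 30% epiboly, against 115, they were 202 with print-tip loess, 378 with scaling between arrays, 3 with separate fits, 3775 with array weights (which favour the first campaign), 35 with collection day as a random block, 41 with arrays of 1 day averaged, 53 with the second campaign alone, 6 with the first alone, 2851 with the first alone and replicate 6 turned, 408 with replicate 6 turned, 257 with replicate 6 turned and the day block, and 31 with 3 arrays per stage. At shield, against 892, they were 5.7e2 (rounded) without background correction, 422 with median centring, 60 with scaling, 527 without a dye term, 232 with separate fits, 83 with array weights, 146 with days averaged, 183 with the second campaign alone, 198 with the value table and 61 with 3 arrays per stage. At tailbud, against 1695, they were 412 with scaling, 576 with separate fits, 403 with array weights, 410 with days averaged, 459 with the second campaign alone, 506 with the value table and 155 with 3 arrays per stage.

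The count of probes that differ between stages, 642, became 148 with scaling, 366 with array weights, 102 with days averaged, 116 with the second campaign alone, 300 with the value table and 27 with 3 arrays per stage. For tailbud against shield, 231 became 444 with print-tip loess, 48 with scaling, 140 without a dye term, 65 with array weights, 85 with the replicate number as a block, 61 with days averaged, 73 with the second campaign alone, 475 with replicate 6 turned and the day block, and 6 with 3 arrays per stage. The replicate number block was run on this count alone. The day block with replicate 6 as labelled moved no count by over 1.5 times apart from that at 30% epiboly.

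Leaving out 1 array at a time gave 50 to 338 calls at 30% epiboly, 416 to 1147 at shield, 1082 to 2037 at tailbud, 469 to 1006 for the difference between stages, 161 to 388 for tailbud against shield and 1458 to 2233 for the std MO change. At 30% epiboly the highest count was without replicate 6, and without any 1 of replicates 4, 5, 7, 8, 9, 10, 11 and 12 it was 50 to 60. Shield fell to 416 without shield replicate 2, tailbud to 1082 without tailbud replicate 2, the difference between stages rose to 1006 without 30% epiboly replicate 1, and tailbud against shield rose to 364 and 388 without tailbud replicates 1 and 3. The gene list tests and their alternatives were not run, because the probes carry no gene symbols here. Median red signal was 1.53 to 4.32 times background on second-campaign arrays, those of 30% epiboly included; how far this limits the calls was not tested.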

Other observations

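The 2 strongly lowered probes were low in both campaigns. In the second campaign alone CGENXEB_456009281_0 stood at -4.04 at 30% epiboly (adjusted p 3.79e-07), -4.2 at shield and -3.5 at tailbud, and in the first campaign alone at -3.04 at 30% epiboly (adjusted p 0.000817). Its spot was saturated on 4 of the 8 usable arrays of 30% epiboly and on 1 of 5 at tailbud, which compresses the ratio there, so the campaigns are not compared by size. CGENXEB_456006350_0 stood at -3.14 in the second campaign at 30% epiboly (adjusted p 2.24e-06) and at -2.06 in the first (adjusted p 0.111), where replicate 6 is the array above 0.

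Embryos without mtx2 function are known to lag in epiboly, so a hypothesis set before its test was that mtx2 MO embryos were behind in development when collected. Then the mtx2 MO effect should oppose the change that std MO embryos undergo toward that stage, measured on other arrays. No stage before 30% epiboly was measured, so the change from 30% epiboly to shield, which follows it, was used there. At tailbud the effect of 6 dye-balanced pairs of arrays correlated with the std MO change from shield to tailbud on the remaining arrays with r from -0.18 to -0.1 across probes (mean -0.13), which is what a delay predicts, although the relation is weak and a loss of transcripts that normally rise would give the same sign. At shield the mean r with the std MO change from 30% epiboly to shield was -0.04 (6 pairs, r from -0.13 to 0.02), which does not decide. At 30% epiboly r with the same change was -0.1 as labelled and -0.11 with replicate 6 turned. The bound set before was an r below -0.1 in both, which was not met as labelled, so this does not decide either. That change also comes after the stage. A delay may thus contribute to the tailbud differences, and it cannot be told apart there from a direct loss or from another effect of the morpholino.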
